A study of Mus musculus with 9 samples.

How the data were processed

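Gene expression was measured in immortalised mouse endothelial cells (EC) of retinal, brain and choroidal origin, with 3 libraries per origin and 9 in all. Per the labels, polyA RNA was sequenced as unamplified cDNA on a nanopore device, with 1 native barcode per library and all libraries on one flow cell. The libraries carry the codes R782 to R784 (retinal EC), R785 to R787 (brain EC) and R788 to R790 (choroidal EC). The labels do not say whether the libraries of an origin come from separate cultures, so the p-values below measure only the spread between these samples, which may be technical. They also do not say whether an origin is represented by more than 1 cell line. No batch, donor or culture date is stated, and no paired analysis was possible because no code is shared by libraries of different origins.

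The deposited gene table holds raw counts, which the authors made with bambu, as the name of the table says, against the build GRCm39. The aligner, the version of bambu and the annotation release are not given in the sources used here. All values were whole numbers, so no rounding was needed. The table has 55460 entries. Of these, 52081 were matched to a gene symbol through their Ensembl ID, and 46 are loci with no reference ID. The deposited sequencing summary lists every read with its length in bases, its mean quality score, whether it passed the quality filter and its barcode, per the file headers. The basecaller is not given in the sources used here, and the values put the pass mark at a mean quality score of 4.

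Total gene counts per library ranged from 576992 to 922057. There were 1.51 gene counts per passed read with 1 of the 9 barcodes (range over libraries 1.41 to 1.59), so the counts are not a simple tally of these reads. A count of 3 over the libraries of an origin, the most that a count of 0 allows, was 1.22 counts per 1e6 counts (CPM) in retinal EC, 1.21 in brain EC and 1.58 in choroidal EC. For a gene at 0 counts in 1 origin, the fold is given as a lower bound against that floor over the group. For 1 to 3 counts, the ratio is given with an exact 95% counting interval. These intervals and floors cover counting error only. They treat each count as an independent read, which 1.51 counts per passed read do not bear out, so they may understate that error. The spread between replicate libraries was larger than counting error: the chi-square per degree of freedom between pairs of replicates was 3.94 to 12.2.

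Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes were kept by filterByExpr with its default minimum count of 10 and minimum total of 15, which left 7026 genes, 27 of them without a reference ID. Library sizes were scaled by TMM, and one quasi-likelihood model with the 3 origins was fitted to all 9 libraries. The biological coefficient of variation was 24.6%. Each pair of origins was compared, and a further F test asked for any difference among the 3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. A gene was taken as set apart in 1 origin when both contrasts of that origin called it in the same direction. CPM values in the text use the TMM-scaled library sizes. Log2 fold changes carry a standard error (SE) derived from the quasi-likelihood F statistic, CPM values a standard deviation (SD), and n is 3 libraries per origin throughout.

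A total of 829 genes in 30 lists were fixed from textbook knowledge. Of these genes, 828 were found in the table and 337 were tested. The 23 lists with at least 5 tested members were tested as sets with camera, with a preset correlation between genes of 0.01 and adjustment over the lists and the 3 contrasts together. The same lists were also tested with camera at an estimated correlation and with fry, which asks whether the genes of a list move on balance one way without comparing them with other genes. The number of members given for a list is that of its tested genes. For example, 7 of 49 cytokine and chemokine genes and 9 of 30 blood-brain barrier genes were tested. Members were counted when called over all genes and when adjusted over the list alone. The sex-linked list was used only as a check of the samples.

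The genes named were chosen by a rule. For each contrast it took the 10 called genes with the largest log2 fold change in each direction that had an official symbol, a mean of at least 20 CPM in the higher group and CPM ranges that did not overlap. It also took up to 4 called members of each list and 25 genes named whatever their result. The grouping, the tests, the thresholds, the lists, the rule for named genes and most alternatives were chosen before the data were examined. Genes named outside the rule are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

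Read counts, lengths and qualities per library were compared by exact two-sided permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1. The alternatives were RLE size factors, no filter on low counts, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the 2 groups compared, removal of loci without a reference ID, removal of mitochondrial and ribosomal protein genes, a test against a log2 fold change of 1, and leaving out each library in turn. Chosen after seeing the data were a robust dispersion, a covariate for the libraries R782, R787 and R789, and a fit without these 3 libraries. They carry barcodes 01 to 03 and differ from the other 6 at several loci. A fit without the genes of 2 chromosome segments was also chosen after seeing the data. The detection of changes was tested on simulated data made from these counts: edgeR called 17.6% to 22.1% of the tested genes with a simulated 2-fold change and 71% to 84.2% of those with a 4-fold change, with 2 to 5 false calls per contrast.

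The order of genes along chromosomes was taken from a reference annotation on GRCm38, an earlier build than that of the counts. It served only to find neighbouring and overlapping genes, and no positions are given. Isoform structure was not analysed here.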

Results

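Gene expression was measured by nanopore cDNA sequencing in immortalised endothelial cells of retinal, brain and choroidal origin, with 3 libraries each. Total gene counts were 862881, 882203 and 786157 in the retinal libraries R782, R783 and R784. They were 834933, 922057 and 687046 in the brain libraries R785, R786 and R787. In the choroidal libraries R788, R789 and R790 they were 731664, 576992 and 756697. The mean was 688451 ± 97334 (SD, n = 3) in choroidal EC against 843747 ± 50801 in retinal EC (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow) and 814679 ± 118807 in brain EC (exact p = 0.3). Passed reads averaged 1504 ± 28.9 bases in choroidal EC, 1614 ± 128 in retinal EC and 1604 ± 73.4 in brain EC (n = 3 each), a difference of -99.7 bases between choroidal and brain EC (exact permutation p = 0.1) and of -109.9 between choroidal and retinal EC (exact permutation p = 0.3). Between 37.7% and 46.3% of the counts of a library fell on 46 loci with no reference ID.

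Retinal and brain EC resembled each other more than either resembled choroidal EC. Across the tested genes, the mean correlation of log2 CPM between a retinal and a brain library was 0.873, close to that within retinal EC (0.888) and within brain EC (0.884). It was 0.812 between choroidal and retinal libraries and 0.817 between choroidal and brain libraries, against 0.863 within choroidal EC. These correlations are across genes, which are not independent replicates. Principal components were computed on the 500 genes of highest variance. The first held 36.3% of the variance of these genes and separated the 3 choroidal libraries from the other 6. The second, with 13.2%, separated R789 from the other choroidal libraries. At an adjusted p under 0.05, 10 genes differed between retinal and brain EC, 361 between choroidal and brain EC and 454 between choroidal and retinal EC. An F test found 411 genes that differed anywhere among the 3 origins.

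The comparison of retinal with brain EC addresses how far endothelial cells of 2 barrier-forming neural tissues differ. Fabp4 (ENSMUSG00000062515.4), a fatty acid binding protein, was higher in retinal EC, at 321.5 ± 32.2 CPM (SD, n = 3) against 104.0 ± 15.7 in brain EC (log2 fold change 1.62 ± 0.17 SE, adjusted p = 0.00317). Flt1 (ENSMUSG00000029648.14), the VEGF receptor that also acts as a decoy for VEGF, was lower, at 87.2 ± 1.62 against 194 ± 20 CPM (-1.15 ± 0.15, adjusted p = 0.0077). Gpm6a, a membrane glycoprotein best known from neurons, was lower too (-3.09 ± 0.38, 13 counts against 116). The secreted chemokine Ccl21a, a marker of lymphatic endothelium, was higher by 2.95 ± 0.50, the growth factor Igf2 by 1.85 ± 0.29, the elastic fibre protein Fbln5 by 1.38 ± 0.22 and the annexin Anxa1 by 1.13 ± 0.19. Of the 10 genes called, 6 were higher and 4 lower in retinal EC. Another called gene was Pgm2l1, which had no counts in retinal EC and is named after its values were seen. The peroxiredoxin Prdx2 was called higher (1.86 ± 0.26) and the ribonuclease subunit Rnaseh2a lower (-2.44 ± 0.31). The bodies of these 2 genes overlap, and their summed counts did not differ by edgeR (log2 fold change 0.328, SE 0.165, adjusted p = 0.646), so both calls are uncertain.

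The pan-endothelial identity list was lower in retinal EC as a set (median log2 fold change -0.341 over 27 tested members, adjusted p = 1.76e-06, and adjusted p = 0.0976 with an estimated correlation). Flt1 was its only member called over all genes, against 5 lower when adjusted over the list alone. The junction protein Cdh5 had a log2 fold change of -0.48 ± 0.16, Pecam1 of -0.23 ± 0.18 and Eng of -0.41 ± 0.20, none of them called. The fenestrated endothelium list was lower in retinal EC (12 members, median -0.392, adjusted p = 4.54e-05) and kept its call with an estimated correlation (adjusted p = 0.0425). Within it Flt1 was called, and adjusted over the list alone 1 member was higher and 3 lower. Plvap, which forms the diaphragms of fenestrae, was at -0.30 ± 0.18. The lymphatic endothelium list was higher (6 members, median 0.734, adjusted p = 2.19e-05, and adjusted p = 0.0725 with an estimated correlation), with Ccl21a called over all genes and 3 members higher when adjusted over the list alone.

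The proliferation and DNA replication list was higher in retinal EC (30 members, median 0.45, adjusted p = 1.17e-08) and kept its call with an estimated correlation (adjusted p = 0.00925). None of its members was called over all genes by edgeR, while 7 were higher when adjusted over the list alone. Among these were the mitotic cyclin Ccnb2 (1.18 ± 0.28), the topoisomerase Top2a (0.92 ± 0.26) and the replication clamp Pcna (0.64 ± 0.20), chosen after their values were seen. Of the remaining lists, 5 were lower in retinal EC with a preset correlation and lost their call with an estimated one. They were tight and adherens junctions (18 members, none called, median -0.252, adjusted p = 0.00607, and adjusted p = 0.138 with an estimated correlation), interferon response (38 members, none called, median -0.324, adjusted p = 0.0118, and adjusted p = 0.151 with an estimated correlation) and basement membrane and matrix (24 members, median -0.244, adjusted p = 0.0144, and adjusted p = 0.142 with an estimated correlation). The Wnt, norrin and beta-catenin list (12 members, none called, median -0.301, adjusted p = 0.0161, and adjusted p = 0.142 with an estimated correlation) and the innate sensing and NF-kappaB list (18 members, none called, median -0.235, adjusted p = 0.0427, and adjusted p = 0.142 with an estimated correlation) completed them. Adjusted over the list alone, 2 interferon members were higher and 2 lower, and 1 matrix member (Fbln5, the only one called over all genes) was higher and 4 were lower.

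None of the HIF1, TGF-beta and VEGF lists named by the study's title was called between retinal and brain EC. The HIF1 and hypoxia response list (25 members, none called over all genes, 2 lower when adjusted over the list alone) had an adjusted p of 0.406, with Hif1a at -0.40 ± 0.19, Epas1 at -0.74 ± 0.18 and the glucose transporter Slc2a1 at 0.26 ± 0.58. The TGF-beta and BMP list (24 members, none called either way) had an adjusted p of 0.366, with Tgfbr2 at -0.57 ± 0.16, Tgfb1 at 0.23 ± 0.48 and Acvrl1 at -0.61 ± 0.19. The VEGF list (35 members, Flt1 called, 2 lower when adjusted over the list alone) had an adjusted p of 0.0879, with Kdr at -0.25 ± 0.17 and Nrp1 at -0.20 ± 0.15. Of the immune genes followed throughout, Ccl2 was at 0.85 ± 0.19, Icam1 at -0.45 ± 0.32, B2m at -0.22 ± 0.22 and H2-K1 at 0.08 ± 0.15. The tight junction gene Cldn5 was at -1.53 ± 0.57. The adjusted p of these genes, which edgeR did not call, ran from 0.175 for Ccl2 to 0.945 for Slc2a1. Without a filter on low counts Ccl2 (adjusted p = 0.0475) and Cldn5 (0.0216) were called, and with a robust dispersion Epas1 (0.0494), each with values up to 1 under other alternatives. Camera made no call for the lists of blood-brain barrier (adjusted p = 0.246), arterial (0.915), venous (0.117), tip cell (0.237) and Notch (0.624) genes. Nor did it call MHC class I (0.742), cytokine and chemokine (0.406), leukocyte adhesion (0.0879) or complement and coagulation (0.156) genes. Regional transcription factor (0.099) and fibroblast (0.474) genes were not called by it either. Fry called the blood-brain barrier and leukocyte adhesion lists lower (adjusted p = 0.0399 for each). The median and the camera test differed in sign for the arterial, HIF1 and MHC class I lists.

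The calls of the 9 genes named by the rule for this comparison were lost without R782, R787 and R789 together, where 2 genes were called, and against a log2 fold change of 1. Fabp4, Gpm6a and Rnaseh2a kept their calls with each library left out in turn. Limma-voom did not call Gpm6a (adjusted p = 0.0904), Fbln5 (0.0904) or Ccl21a (0.225), and with a covariate for those 3 libraries Ccl21a (0.0869) and Anxa1 (0.0517) were not called. Flt1 lost its call without R783 (adjusted p = 0.0683, range over the 9 libraries 0.0139 to 0.0683) and Prdx2 without R783 or R787 (0.052 and 0.107, range 0.00302 to 0.107). Anxa1 lost it without each library but R790 (0.101, 0.218, 0.0653, 0.176, 0.14, 0.152, 0.054 and 0.055 from R782 to R789, range 0.0214 to 0.218) and Ccl21a without each but R789 (0.206, 0.264, 0.0973, 0.176, 0.0621, 0.152, 0.0596 and 0.0721 in the same order, range 0.0285 to 0.264). Fbln5 lost it without R782 to R788 (0.0519, 0.0781, 0.102, 0.148, 0.125, 0.125 and 0.054, range 0.0198 to 0.148) and Igf2 without each but R786 and R789 (0.0677, 0.0781, 0.116, 0.153, 0.152, 0.054 and 0.0564, range 0.0158 to 0.153). The interferon call was lost without R787 (adjusted p = 0.0883), the innate sensing call without R782, R783 or R786 (0.0835, 0.0589 and 0.126), the Wnt call without R783 or R787 (0.0618 and 0.0716) and the matrix call without R782, R785 or R786 (0.067, 0.08 and 0.0578). These 4 list calls were also lost without R782, R787 and R789 together, and the call of the tight and adherens junctions list with each gene counted in 1 list only (0.227).

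**Figure D1:**
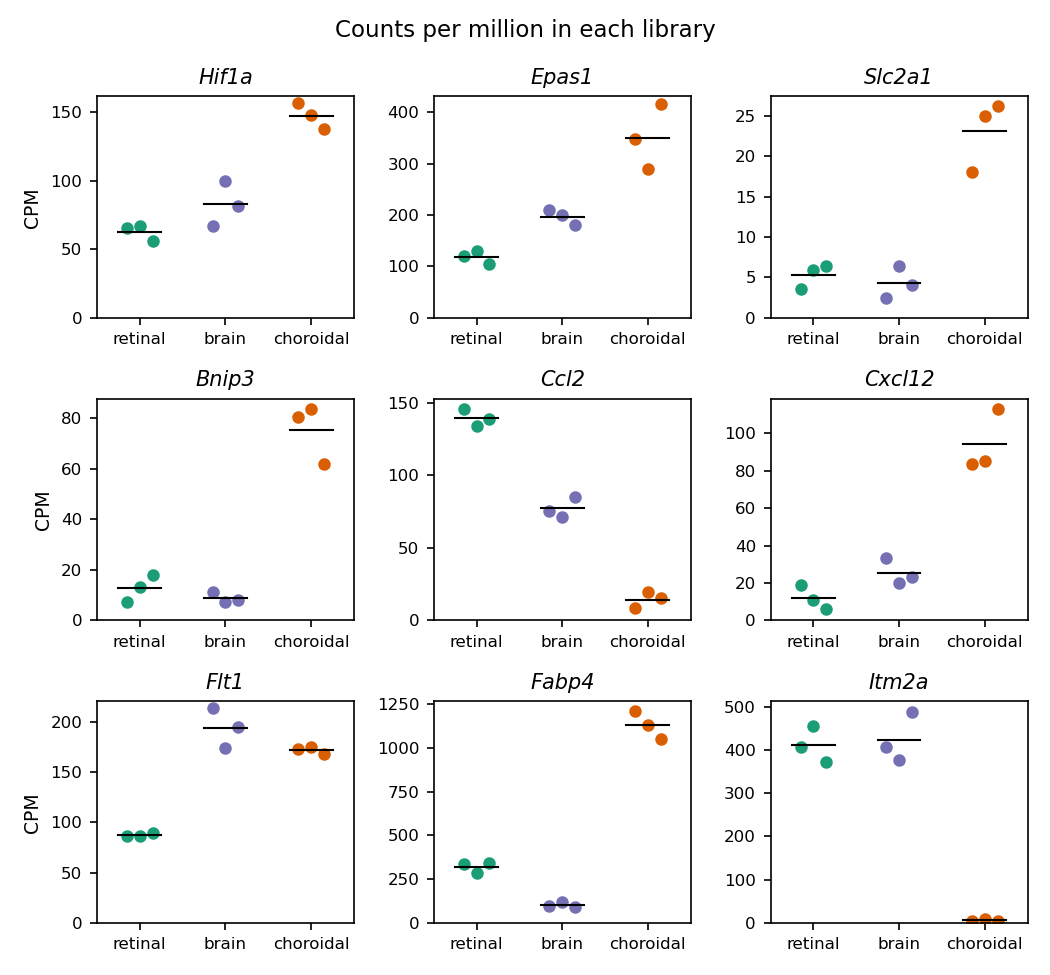
CPM (vertical axis, from 0) of 9 genes in each of the 9 libraries, as dots grouped by origin, with a line at the mean of the 3 libraries. Hif1a, Epas1, Slc2a1, Bnip3 and Cxcl12 are highest in the 3 choroidal libraries, and Ccl2 and Itm2a are lowest there.

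The comparison of choroidal with brain EC sets cells that originate from a leaky, fenestrated bed against cells from a barrier-forming one. Whether the immortalised cells kept these traits was not measured. Itm2a (ENSMUSG00000031239.6), a membrane protein used as a marker of brain endothelium, was lower in choroidal EC at 5.99 ± 2.55 CPM against 423 ± 57.6 (log2 fold change -6.14 ± 0.27, adjusted p = 8.98e-08). The matrix proteoglycan Bgn (ENSMUSG00000031375.18) was higher at 208.7 ± 21.3 CPM against 5.38 ± 2.91 (5.18 ± 0.35, adjusted p = 3.92e-06). The HIF1 and hypoxia response list was higher in choroidal EC as a set, while the chemokine Ccl2 (ENSMUSG00000035385.6), which attracts monocytes, was lower at 14.3 ± 5.73 CPM against 77.3 ± 7.3 (-2.42 ± 0.25, adjusted p = 0.000132). Of the 361 genes called, 185 were higher and 176 lower in choroidal EC, against 201 and 106 with limma-voom.

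Among the largest differences, Xlr was at least 32.8-fold, Meox1 at least 23.2-fold and Hoxd8 at least 18.4-fold higher in choroidal EC, since brain EC had no counts of them. The latter 2 are homeobox transcription factors. Ifi27l2b was higher with a ratio of 69.6 (95% counting interval 12 to 2800), and the lipid-metabolism regulator Pparg with a ratio of 43.8 (14.6 to 216). The monoglyceride lipase Mgll was higher by 4.84 ± 0.37, the MHC class I gene H2-T24 by 4.86 ± 0.51 and the erythropoietin receptor Epor by 4.59 ± 0.64. Xlr, Ifi27l2b and H2-T24 have close paralogs, and how reads were shared between these is open. In the other direction, choroidal EC had no counts of Lrrn1, Gng2, Rcsd1 and N-cadherin (Cdh2), which were at least 27.4-fold, 20-fold, 15-fold and 14.5-fold lower. Pcp4l1 was lower by -6.47 ± 0.48 and the creatine transporter Slc16a12 with a ratio of 60.1 (10.5 to 2400). Meox1 lies in a chromosome 11 segment whose genes were lower in choroidal EC (median -0.602), and moved against it.

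The HIF1 and hypoxia response list was higher in choroidal EC (25 members, median 0.828, adjusted p = 5.55e-11) and kept its call with an estimated correlation (adjusted p = 0.00764). Over all genes 10 members were higher and none lower, against 14 higher and none lower when adjusted over the list alone. Bnip3 (ENSMUSG00000078566.9), a mitophagy receptor and known HIF1 target, rose from 8.89 ± 1.97 CPM in brain EC to 75.4 ± 11.7 in choroidal EC (3.06 ± 0.33, adjusted p = 0.000162). The glycolytic enzymes Pfkl (1.49 ± 0.23), Tpi1 (1.31 ± 0.19) and Aldoa (1.11 ± 0.17) were higher, as was Slc2a1 (2.36 ± 0.50, 44 counts against 11). Hif1a (ENSMUSG00000021109.14) was at 147.3 ± 9.2 CPM against 82.6 ± 16.5 (0.83 ± 0.18, adjusted p = 0.0178) and Epas1 (ENSMUSG00000024140.11), which encodes HIF2-alpha, at 350.1 ± 63.3 against 197.1 ± 14.5 (0.83 ± 0.17, adjusted p = 0.0142). The HIF target Vegfa was below the filter, with 23 counts in choroidal and 16 in brain EC.

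The angiogenic tip cell list was higher in choroidal EC (16 members, 4 higher and none lower, median 0.474, adjusted p = 0.000533, and adjusted p = 0.053 with an estimated correlation), with 7 higher and 2 lower when adjusted over the list alone. The membrane metalloproteinase Mmp14 was higher by 3.23 ± 0.27 and the basement membrane collagens Col4a2 by 1.08 ± 0.15 and Col4a1 by 0.80 ± 0.15. The basement membrane and matrix list was higher too (24 members, 7 higher and 3 lower, median 0.405, adjusted p = 0.0118, and adjusted p = 0.139 with an estimated correlation). Adjusted over the list alone 10 were higher and 6 lower. Besides Mmp14, Fbln5 was higher by 2.66 ± 0.21 and Col18a1, the source of endostatin, by 1.91 ± 0.24, while Col15a1 was lower at -2.97 ± 0.23. Of the identity lists, the arterial list was higher (9 members, Fbln5 and Cxcl12 called higher and none lower, 2 higher and 1 lower when adjusted over the list alone, median 0.371, adjusted p = 0.0224, and adjusted p = 0.139 with an estimated correlation). The lymphatic list was lower (6 members, Mmrn1 called, 4 lower when adjusted over the list alone, median -1.02, adjusted p = 0.00607, and adjusted p = 0.142 with an estimated correlation). The blood-brain barrier list was lower by its test, though its median was near 0 (9 members, 1 higher and 2 lower, 2 and 3 when adjusted over the list alone, median -0.0495, adjusted p = 0.0118, and adjusted p = 0.124 with an estimated correlation). Its members Itm2a and the lipid transfer protein Pltp (-2.96 ± 0.33) were lower and Slc2a1 was higher.

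Of the immune lists, cytokines and chemokines were lower in choroidal EC (7 members, 1 higher and 3 lower, 2 and 4 when adjusted over the list alone, median -1.57, adjusted p = 0.0124, and adjusted p = 0.142 with an estimated correlation). Ccl2 and the death ligand Tnfsf10 (-3.24 ± 0.47) were lower, while Cxcl12 (ENSMUSG00000061353.12), a homeostatic chemokine, was higher at 94.1 ± 16.4 CPM against 25.5 ± 6.96 (1.89 ± 0.30, adjusted p = 0.00246). The complement and coagulation list was higher (14 members, 4 higher and 1 lower, 4 and 2 when adjusted over the list alone, median 0.139, adjusted p = 0.0413, and adjusted p = 0.23 with an estimated correlation). The plasminogen activator Plau (3.92 ± 0.36), the complement inhibitor Cd55 (1.85 ± 0.29) and the protein C receptor Procr (1.38 ± 0.22) were higher. The interferon list was not called (adjusted p = 0.237, 1 higher and 1 lower of 38 both ways of adjusting), nor was MHC class I (0.775, H2-T24 higher and H2-K1 lower of 17 both ways), leukocyte adhesion (0.639, 1 higher and 2 lower of 20, 7 and 3 when adjusted over the list alone) or innate sensing (0.644, none called over all genes). H2-K1 was at -0.58 ± 0.15 (adjusted p = 0.0465).

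Camera did not call the TGF-beta and BMP list between choroidal and brain EC (adjusted p = 0.0879). Of its 24 members 2 were higher over all genes and 5 when adjusted over the list alone. Fry called the list higher (adjusted p = 0.0399). The secreted follistatin-like protein Fstl1 (1.39 ± 0.20) and Id2 (1.70 ± 0.38) were higher, Tgfbr2 was at 0.58 ± 0.16 (adjusted p = 0.0606), Eng at 0.47 ± 0.20, Acvrl1 at -0.38 ± 0.19 and Tgfb1 at -0.29 ± 0.51. The VEGF list was not called either (adjusted p = 0.995, 1 higher of 35, and 1 higher and 3 lower when adjusted over the list alone). Its called member was the phosphatase Ptprb (1.40 ± 0.22), while Kdr (0.05 ± 0.17), Flt1 (-0.18 ± 0.15) and Nrp1 (0.11 ± 0.15) were not called. Also not called by edgeR were Cdh5 (0.47 ± 0.16), Pecam1 (-0.48 ± 0.18), Cldn5 (-2.36 ± 0.66, adjusted p = 0.0613), Plvap (-0.05 ± 0.18), Icam1 (-0.12 ± 0.33) and B2m (-0.36 ± 0.22). Pecam1 lies in the chromosome 11 segment. Other settings called 3 of these genes. Cldn5 was called by DESeq2 (adjusted p = 0.0183), without a filter on low counts (1.55e-05), without R785 (0.00825) and with the covariate for R782, R787 and R789 (0.0239), with a highest value of 0.534 over all alternatives. Tgfbr2 was called by limma-voom (0.0387), with a robust dispersion (0.0318) and with the covariate (0.0489), and Cdh5 by limma-voom (0.0459) and with a robust dispersion (0.0371), both with values up to 1 elsewhere. Camera did not call the lists of pan-endothelial identity (adjusted p = 0.376), fenestrated endothelium (0.797), venous endothelium (0.0559), Wnt (0.474) or Notch (0.995). Nor did it call tight and adherens junctions (0.0879), proliferation (0.915), regional transcription factors (0.165) or fibroblast genes (0.899). Fry called the venous (adjusted p = 0.0126) and junction (0.0165) lists lower and the regional transcription factor list higher (0.0399). In the fenestrated list the lipoprotein lipase anchor Gpihbp1 was higher (3.72 ± 0.29) and Igfbp5 lower (-1.15 ± 0.16). The median and the test differed in sign for the VEGF, innate sensing, proliferation and fibroblast lists, and the median and the mean for Notch.

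Slc2a1 lost its call without R785, R787, R789 or R790 (adjusted p = 0.0745, 0.0605, 0.061 and 0.0697, range over the 9 libraries 0.0225 to 0.0745), Hif1a without R785, R787 or R788 (0.088, 0.0653 and 0.0677, range 0.0192 to 0.088), Epas1 without R786, R787 or R790 (0.0585, 0.0653 and 0.052, range 0.00956 to 0.0653), Id2 without R785, R787, R789 or R790 (0.0716, 0.0504, 0.0718 and 0.0707, range 0.0195 to 0.0718), Mmrn1 without R785, R789 or R790 (0.0503, 0.0549 and 0.058, range 0.0108 to 0.058), Hoxd8 and Col4a1 without R786 (0.0504 and 0.054) and H2-K1 without each of the 9 (0.0624 to 0.143). By list, the arterial call was lost without R786, R787 or R790 (0.0963, 0.0563 and 0.145), the matrix call without R787 (0.0838) and the complement call without R782, R783, R784, R786, R787, R788 or R789 (0.0916, 0.108, 0.0864, 0.136, 0.0985, 0.141 and 0.0808). DESeq2 did not call Hif1a (adjusted p = 0.0544) or H2-K1 (0.116), and limma-voom did not call 21 of the 62 called genes that the rule named, among them Pparg, Epor, Meox1, Cdh2, Gng2, Rcsd1, Slc16a12, Tnfsf10, Mmrn1 and Slc2a1 (0.0563 to 0.294). Without R782, R787 and R789 together 15 of the 62 were lost, among them Hif1a (adjusted p = 0.12), Slc2a1 (0.131), Id2 (0.133), Hoxd8 (0.0603), Mmrn1 (0.0569) and H2-K1 (0.197), as was the call of the complement and coagulation list (0.109). With the filter of 5 CPM in 3 libraries the calls of the cytokines and chemokines list (0.0543) and of the complement and coagulation list (0.0754) were lost, and the latter also without the genes of the 2 chromosome segments (0.0551). The call of the basement membrane and matrix list was lost with each gene counted in 1 list only (0.576).

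Choroidal and retinal EC come from neighbouring layers of the eye, and this comparison asks how far their endothelia differ. It gave the most calls of the 3 pairs, with 237 genes higher and 217 lower in choroidal EC, against 226 and 133 with limma-voom. Lgals1 (ENSMUSG00000068220.7), a secreted galectin, was at 434.4 ± 36.8 CPM in choroidal EC against 13.3 ± 5.26 in retinal EC (5.01 ± 0.27, adjusted p = 5.53e-07). Ccl2 was at 14.3 ± 5.73 against 139.4 ± 5.91 CPM (-3.27 ± 0.24, adjusted p = 6.5e-06). The TGF-beta receptor Tgfbr2 (ENSMUSG00000032440.14) was higher at 224.3 ± 15.6 against 100.8 ± 13.5 CPM (1.15 ± 0.16, adjusted p = 0.000998), and so were Hif1a and Epas1.

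Choroidal EC had at least 37.7-fold more Rtl8c, 32.5-fold more Xlr, 26.9-fold more Pgm2l1 and 23-fold more Ifi27l2b, of which retinal EC had no counts. H2-T24 was higher with a ratio of 185 (95% counting interval 32.6 to 7350) and Epor with a ratio of 52.7 (14.1 to 443). Bgn was higher by 6.57 ± 0.41, Gpihbp1 by 4.99 ± 0.33 and Xist, the RNA that silences an X chromosome, by 4.98 ± 0.55. Reads may be shared with paralogs for Rtl8c, Xlr, Ifi27l2b and H2-T24, which was not resolved. Retinal EC had Rcsd1, the neuropeptide gene Nts, Gng2 and Lrrn1, of which choroidal EC had no counts, so that these were at least 20-fold, 16.4-fold, 14.3-fold and 13.6-fold lower in choroidal EC. Itm2a (-6.10 ± 0.27) and Pcp4l1 (-6.71 ± 0.48) were lower, and so was the apolipoprotein Apoe with a ratio of 27.9 (9.3 to 137).

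The HIF1 and hypoxia response list was higher in choroidal EC (25 members, median 0.807, adjusted p = 8.63e-12) and kept its call with an estimated correlation (adjusted p = 0.00764). Over all genes 10 members were higher and none lower, and 13 and 1 when adjusted over the list alone. Epas1 was higher by 1.57 ± 0.18, Hif1a by 1.23 ± 0.18, Pfkl by 2.19 ± 0.24, Bnip3 by 2.56 ± 0.31, Tpi1 by 1.30 ± 0.19 and Slc2a1 by 2.10 ± 0.49. The angiogenic tip cell list was higher and kept its call as well (16 members, 7 higher and 1 lower, 9 and 2 when adjusted over the list alone, median 0.773, adjusted p = 3.22e-05, and adjusted p = 0.0425 with an estimated correlation). Mmp14 (2.77 ± 0.26), Col4a2 (1.49 ± 0.15), Col4a1 (1.14 ± 0.15) and Sparc (0.87 ± 0.16) were higher, and Flt4, the receptor of lymphatic growth factors, was lower at 66.8 ± 20.9 CPM against 135.1 ± 20.7. The lymphatic endothelium list was lower and kept its call (6 members, 4 lower and none higher, 5 lower when adjusted over the list alone, median -2.40, adjusted p = 2.76e-07, and adjusted p = 0.0437 with an estimated correlation). Besides Flt4, Ccl21a (-4.17 ± 0.62), the guidance ligand Sema3d (-4.03 ± 0.58) and the matrix protein Mmrn1 (-3.80 ± 0.47) were lower.

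The TGF-beta and BMP list was higher in choroidal EC (24 members, 4 higher and none lower, 7 and 2 when adjusted over the list alone, median 0.227, adjusted p = 0.0224, and adjusted p = 0.16 with an estimated correlation). Tgfbr2, Fstl1 (1.80 ± 0.21), the co-receptor Eng (0.88 ± 0.20, adjusted p = 0.0193) and the pseudoreceptor Bambi (1.61 ± 0.37) were higher, while Acvrl1 (0.23 ± 0.19) and Tgfb1 (-0.53 ± 0.50) were not called. The VEGF list was not called (adjusted p = 0.331, 2 higher and 1 lower of 35 over all genes, 2 and 2 when adjusted over the list alone). Its called members were Ptprb (2.30 ± 0.23) and Flt1 (0.98 ± 0.15, adjusted p = 0.00177), which were higher, and Flt4, which was lower, while Kdr (0.30 ± 0.17) and Nrp1 (0.31 ± 0.15) were not called. The Wnt, norrin and beta-catenin list was higher (12 members, the frizzled receptors Fzd6 and Fzd4 called, 3 higher when adjusted over the list alone, median 0.349, adjusted p = 0.0235, and adjusted p = 0.155 with an estimated correlation), with Fzd6 at 1.85 ± 0.40 and Fzd4, the norrin receptor, at 1.24 ± 0.27. The pan-endothelial list was higher (27 members, 9 higher and none lower, 12 and 1 when adjusted over the list alone, median 0.431, adjusted p = 7.62e-05, and adjusted p = 0.139 with an estimated correlation), with Cdh5 (0.96 ± 0.16) and Cd93 (1.07 ± 0.16) among its called members and Pecam1 (-0.25 ± 0.18), Cldn5 (-0.83 ± 0.75) and Plvap (0.24 ± 0.19) not called. The arterial list was higher (9 members, 2 higher and none lower both ways of adjusting, median 0.52, adjusted p = 0.0412, and adjusted p = 0.142 with an estimated correlation).

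The basement membrane and matrix list was higher (24 members, 10 higher and 4 lower, 12 and 4 when adjusted over the list alone, median 0.679, adjusted p = 4.54e-05, and adjusted p = 0.0601 with an estimated correlation), with Col18a1 (2.96 ± 0.26) and Fbln5 (1.28 ± 0.19) higher and Col15a1 (-2.17 ± 0.24) lower. The complement and coagulation list was higher (14 members, 5 higher and 1 lower both ways of adjusting, median 0.305, adjusted p = 0.00522, and adjusted p = 0.139 with an estimated correlation), with Cd55 (3.60 ± 0.34), Plau (3.21 ± 0.33) and Procr (1.65 ± 0.22). The proliferation list was lower (30 members, 1 higher and 3 lower, 1 and 7 when adjusted over the list alone, median -0.525, adjusted p = 0.00159, and adjusted p = 0.053 with an estimated correlation). Ccnd2 (1.09 ± 0.17) was higher and Birc5 (-1.35 ± 0.28), Ccne2 (-2.36 ± 0.57) and Top2a (-1.09 ± 0.28) were lower. Birc5 and Top2a lie in the chromosome 11 segment lower in choroidal EC.

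Camera called none of the remaining immune lists between choroidal and retinal EC. They were cytokines and chemokines (adjusted p = 0.0772, 1 higher and 3 lower of 7 over all genes) and interferon (0.742, 1 higher and 2 lower of 38). MHC class I (0.915, 1 higher and 1 lower of 17), leukocyte adhesion (0.107, 6 higher and 1 lower of 20) and innate sensing (0.527, none called by edgeR) completed them. Fry called cytokines and chemokines lower (adjusted p = 0.0126) and leukocyte adhesion higher (0.0116). Cxcl12 was higher by 2.95 ± 0.33 and the antiviral tetherin Bst2 by 1.01 ± 0.18, while Tnfsf10 (-2.71 ± 0.50), Ifi27l2a (-1.64 ± 0.29) and Lgals3bp (-3.24 ± 0.60) were lower. Ifi27l2a has a close paralog in Ifi27l2b, which moved the other way, and Lgals3bp lies in the chromosome 11 segment. H2-K1 was lower (-0.67 ± 0.15, adjusted p = 0.0203), and Icam1 (0.32 ± 0.34) and B2m (-0.14 ± 0.22) were not called. Camera also left uncalled the lists of blood-brain barrier (adjusted p = 0.0895), fenestrated (0.0559), venous (0.406) and Notch (0.771) genes. The same held for junction (0.983), regional transcription factor (0.66) and fibroblast (0.902) genes. Fry called the blood-brain barrier list lower (adjusted p = 0.0019) and the fenestrated list higher (0.00286). The median and the camera test differed in sign for the blood-brain barrier, venous, junction and regional transcription factor lists. The median and the mean did so for MHC class I and fibroblast genes.

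Slc2a1 lost its call without R782, R783, R784, R789 or R790 (adjusted p = 0.0887, 0.0745, 0.0601, 0.0728 and 0.0976, range over the 9 libraries 0.0281 to 0.0976), Eng without R782, R783, R788 or R790 (0.0852, 0.0946, 0.0643 and 0.0616, range 0.0125 to 0.0946), Bambi without R783, R784 or R788 (0.0813, 0.0733 and 0.088, range 0.0185 to 0.088), Fzd6 without R783 or R788 (0.0699 and 0.0643, range 0.00638 to 0.0699), Fzd4 without R783, R784 or R788 (0.0591, 0.0713 and 0.0719, range 0.0054 to 0.0719), Flt4 without R784 or R789 (0.0815 and 0.0522, range 0.031 to 0.0815), Birc5 without R782 or R790 (0.052 and 0.0607, range 0.00979 to 0.0607), H2-K1 without R782, R783, R789 or R790 (0.0503, 0.0896, 0.0529 and 0.0844, range 0.0305 to 0.0896), Top2a without R783, R784, R785, R788, R789 or R790 (0.0887, 0.144, 0.0543, 0.135, 0.0632 and 0.0722, range 0.0267 to 0.144) and Ccne2 without R782, R783, R784, R788, R789 or R790 (0.0858, 0.0833, 0.0733, 0.092, 0.0763 and 0.0622, range 0.0149 to 0.092). The arterial call was lost without R783, R784 or R790 (0.0966, 0.0506 and 0.145) and the TGF-beta call without R790 (0.0522), and limma-voom did not call 21 of the 75 called genes that the rule named, among them Rtl8c, Apoe, Gng2, Lrrn1, Ccl21a, Sema3d, Mmrn1, Tnfsf10, Lgals3bp, Ccne2, Top2a, Slc2a1 and Xist (0.0634 to 0.221). Without R782, R787 and R789 together 17 of the 75 were lost, among them Slc2a1 (adjusted p = 0.184), Eng (0.0691), Flt4 (0.0723), Fzd6 (0.0531), Tnfsf10 (0.0627), Ccne2 (0.191) and H2-K1 (0.0868), as was the call of the TGF-beta and BMP signalling list (0.0968), which was also lost with each gene counted in 1 list only (0.0571).

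**Figure D2:**
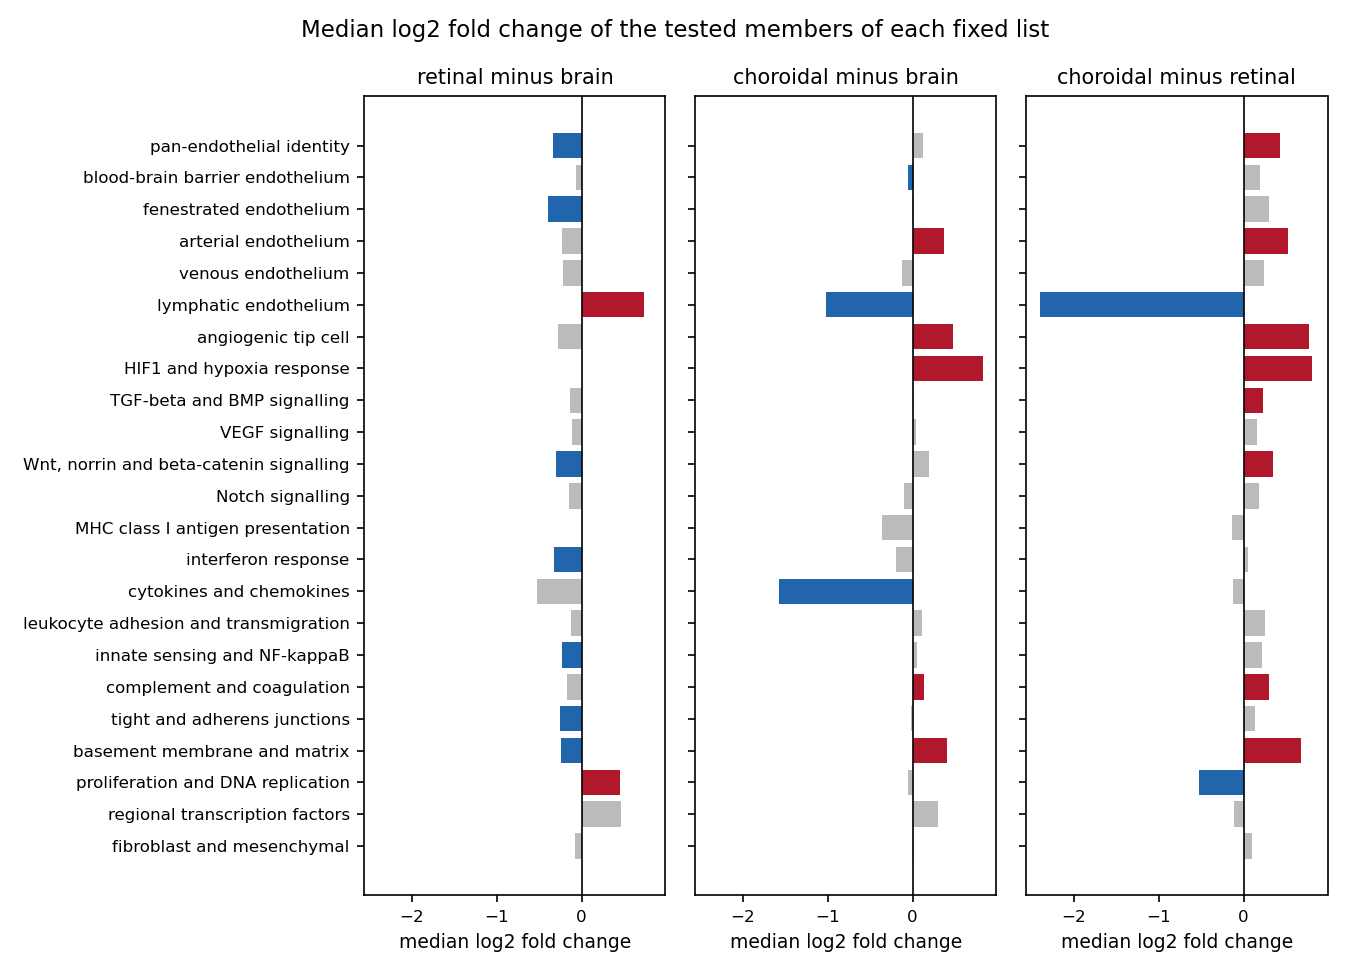
Median log2 fold change (horizontal axis) of the tested members of 23 gene lists, as bars, in the 3 comparisons. Red bars mark lists called higher by camera with a preset correlation of 0.01, blue bars lists called lower and grey bars lists not called, and the bar for the HIF1 and hypoxia response list is 0.828 for choroidal minus brain EC and 0.807 for choroidal minus retinal EC.

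Genes that marked 1 origin against both others were counted next. Choroidal EC were set apart by 245 genes, 119 higher and 126 lower, where independent call lists would share 6.24 and 5.44. With limma-voom 137 were higher and 73 lower, and without the genes of the 2 chromosome segments 105 and 81. Brain EC were set apart by 6 genes. Of these Gpm6a and Rnaseh2a were higher and Fabp4, Fbln5, Igf2 and Prdx2 lower than in both other origins. Rnaseh2a and Prdx2 overlap, which makes their place among the 6 uncertain. By edgeR their summed counts were not called against brain EC in retinal EC (log2 fold change 0.328, adjusted p = 0.646) or choroidal EC (0.110, adjusted p = 0.807). Retinal EC were set apart by 4 genes, with Anxa1 and Ccl21a higher and Flt1 and Pgm2l1 lower. In 20 simulations of unchanged groups, retinal EC were set apart by at most 1 gene and the other origins by none by edgeR. The simulations drew each gene independently, without differences that many genes of a library share. They therefore cannot decide whether the 4 and 6 genes exceed chance. A regrouping of the real libraries that mixed the origins set up to 5 genes apart. Part of any excess over the independent expectation comes from the libraries that the contrasts of an origin share. Fabp4 stood in 3 steps, at 104.0 ± 15.7 CPM in brain, 321.5 ± 32.2 in retinal and 1129 ± 79.1 in choroidal EC (n = 3 each), with each pair called. Genes at 0 counts in the 3 choroidal libraries and at 10 CPM or more in each of the other 6 were Gng2, Lrrn1, Rcsd1 and Rps4l.

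Transcripts of other cell types were few. Of the pericyte and smooth muscle list only Mylk was tested (110 counts in choroidal, 26 in brain and 28 in retinal EC, called higher in choroidal EC in both contrasts). Its call against retinal EC was lost without R790 (adjusted p = 0.051, range over the 9 libraries 0.00327 to 0.051), and both calls were lost without R782, R787 and R789 together (0.0651 against brain EC and 0.097 against retinal EC). Tagln had 23 counts in choroidal EC and none in the others. Of the 26 fibroblast and mesenchymal genes 7 were tested, with Vim at 2154, 2202 and 2144 counts in choroidal, brain and retinal EC and Snai1 at 76, 45 and 36. Counts in this paragraph are not scaled, and 3 counts stand for 1.58 CPM in choroidal, 1.21 in brain and 1.22 in retinal EC. Against retinal EC, 1 of the 7 was called higher in choroidal EC, Snai1, and 1 lower. The Snai1 call was lost without 8 of the 9 libraries (adjusted p range over the 9 by edgeR 0.00618 to 0.148). Of the retinal neuron and glia genes only the glutamine synthetase Glul was tested, which endothelial cells also express. It was higher in choroidal EC than in brain EC (1.44 ± 0.23) and in retinal EC (2.08 ± 0.24). No gene of the retinal pigment epithelium and melanocyte, macrophage and microglia, or epithelial lists passed the filter. Of the MHC class II genes only Cd40 was tested (48, 94 and 111 counts in choroidal, brain and retinal EC), and Cd74 had no counts in any library. Among the genes to be named whatever their result, Tgfb2 had 24 counts in retinal, 2 in brain and 5 in choroidal EC, Tgfbr1 24, 21 and 18, Smad3 13, 13 and 15, and Vcam1 0, 5 and 0, all below the filter. Vegfa had 16 counts in retinal EC. Xist had 226 counts in choroidal, 27 in brain and 9 in retinal EC. The Y-linked genes had 1 count in all, of Ddx3y in brain EC.

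Genes that neighbour each other on 2 chromosomes were lower together in choroidal EC. A search along the gene order, made after the values were seen, found 144 consecutive tested genes on chromosome 4, from Eif3i to Isg15, with a median log2 difference of -0.821 from the mean of the other 2 origins, and 219 on chromosome 11, from Mrpl10 to Wdr45b, with a median of -0.602. Of them 93.1% and 90.4% were below 0. The segments held 59 of the 176 genes called lower than in brain EC and 64 of the 217 called lower than in retinal EC. No such run stood out between retinal and brain EC. The medians in the single choroidal libraries were -0.824, -0.732 and -0.637 on chromosome 4 and -0.494, -0.615 and -0.553 on chromosome 11. Isg15 and Agrn, of the interferon and matrix lists, lie in the first segment, and Pecam1, Jup, Lgals3bp, Birc5, Top2a and Meox1 in the second.

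**Figure D3:**
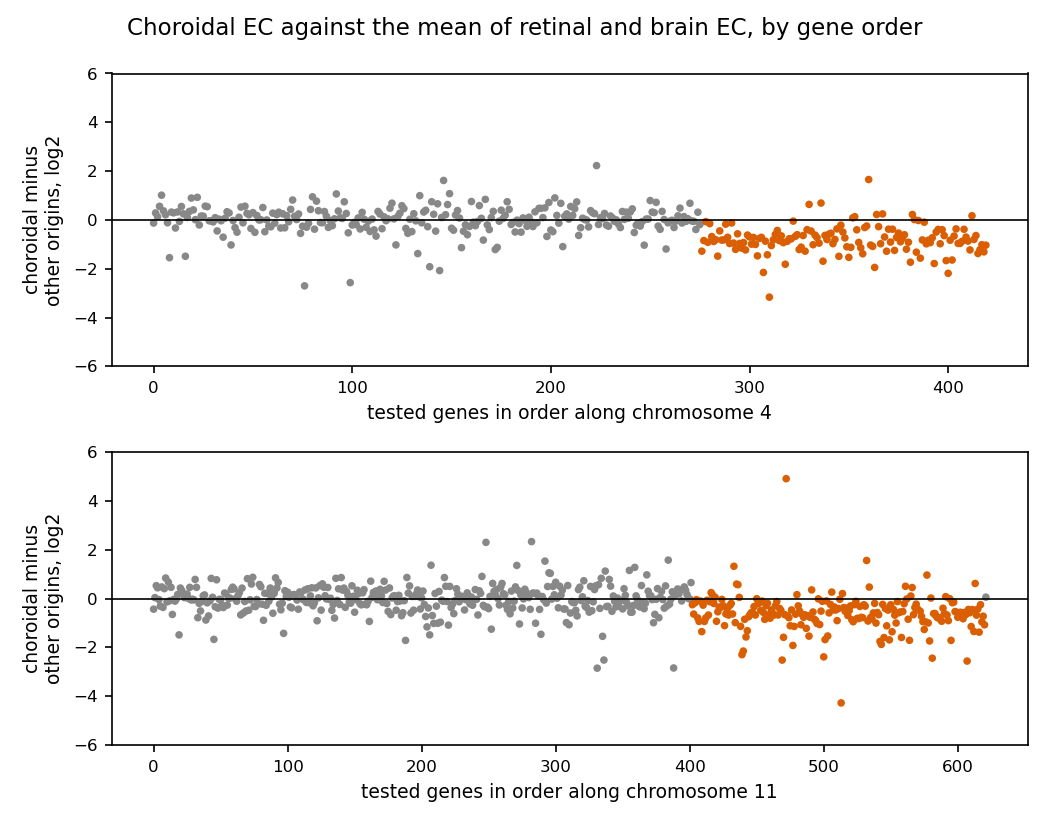
Log2 difference of choroidal EC from the mean of retinal and brain EC (vertical axis) for each tested gene of chromosomes 4 and 11, in gene order (horizontal axis). Orange dots are the 144 and 219 genes of the segments, whose medians are -0.821 and -0.602, and grey dots are the other genes.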

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

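The shuffles of gene order, the lower-dosage test the tests of overlapping genes and the look at which libraries the partitions keep together were chosen only after the results were seen, while the tests of depth, abundant loci, GC content and other splits of the libraries were planned. The sequencing summary holds reads that the gene comparisons do not use, and these were above the 3 that a count of 0 allows. No barcode was assigned to 1253635 reads, 21.2% of all, with a mean quality of 6.90 and a median length of 697 bases. A further 1797 reads carried 1 of 15 barcodes that belong to no sample, at most 377 for a single barcode, which is 0.0385% of the barcoded reads. No biological explanation was tested for either.

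Neighbouring genes on chromosomes 4 and 11 were lower together in choroidal EC, by medians of -0.821 over 144 genes and -0.602 over 219. The weaker segment scored -14.21, which 0 of 1000 shuffles of the gene order reached (highest in size 5.55), and genes outside the segments with the same GC content had a median of 0.039, which argues against a chance order and against GC content. A candidate explanation is that the choroidal cells carry these segments at a lower dosage. It predicts that genes left out of the search are lower in a left-out library as well, and their highest median over libraries and segments was -0.411. Those genes lie within the segments found, so any segment-wide difference shared by the choroidal libraries would give this too. The value therefore does not single out dosage. Regulation of whole segments was not tested and stays open, as does a difference of strain or donor, and the dosage of DNA was not measured.

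Prdx2 was called higher and Rnaseh2a lower in retinal than in brain EC, and the bodies of these genes overlap. Their summed counts differed by a log2 fold change of only 0.328 (SE 0.165, adjusted p = 0.646), so a candidate explanation is that reads were assigned to one gene or the other. Within origins the 2 genes were not opposed (r = -0.079). Over all tested genes, 5.79% of the 466 neighbouring pairs with overlapping bodies were opposed at r below -0.8, against 1.36% of the 6481 pairs that lie apart and at most 4.08% in 100 random draws. Over all neighbouring pairs together the share was 1.66%, no higher than in shuffled orders (highest 2.07%).

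Choroidal EC were set apart by 245 genes. With all libraries thinned to one total, 194 of these genes remained, and without the 4 most abundant loci, which took 39.3% to 48.9% of the counts of a library, 244 remained. These values argue against lower depth or a few abundant loci as the whole cause. Tissue origin stays open and untested. It cannot be separated here from a difference between single cell lines, donors, strains or sexes, since each origin has libraries under 1 label.

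Other splits of the libraries were compared with the real one. For the pairs of origins there are 10 splits of 6 libraries, too few for a share under 0.05, and only 1 gave as many genes or lists, the real one. The real split called 10 genes between retinal and brain EC (highest other 4), 361 between choroidal and brain EC (highest other 1) and 454 between choroidal and retinal EC (highest other 2). For lists the values were 9, 8 and 10 (highest other 2, 2 and 3). Among 100 partitions of the 9 libraries, only the real one gave as many as the 411 genes that differed anywhere (1 partition as high, highest other 247). The same held for the 245 set apart in choroidal EC (1 partition, highest other 216). A random assignment of these libraries to origins is thus unlikely to give such counts. A chance difference between single cultures or lines cannot be excluded, since the libraries of an origin may come from 1 culture. The planned criterion was a share under 0.05. The 4 genes set apart in retinal EC missed it (5 partitions as high, highest other 216), so random grouping stays possible there. The 6 in brain EC met it (3 partitions, highest other 216). Of the 4 other partitions as high as retinal EC, 2 keep the choroidal libraries as a group. The other 2 keep R782, R787 and R789, which mix the origins. Both other partitions as high as brain EC keep the choroidal libraries. Only 2 of the other partitions drawn keep these as a group, and the rest mix them with other origins. The brain result is therefore not taken as decided. In simulations of unchanged groups at most 1 gene was set apart in retinal and 0 in brain EC. These drew each gene independently, without differences shared across a library, so they do not decide it either. In 4 of the partitions R782, R787 and R789 formed a group, with at most 5 genes called.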

How the results depend on the processing

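The robust dispersion, the covariate and fit for R782, R787 and R789, and the fit without segment genes were chosen after the results were seen. No named gene called with the settings of the report changed direction under any alternative run. The alternative without rounding did not apply, since all counts were whole, and neither a fit of 2 groups nor a test against a minimum fold change applies to the question over 3 origins.

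Without a filter on low counts, 129 genes were called between retinal and brain EC, 639 between choroidal and brain EC, 683 between choroidal and retinal EC and 837 anywhere, and 65, 47 and 389 were set apart in retinal, brain and choroidal EC. The cause was not tested. DESeq2 called 16 genes between retinal and brain EC and set 7 apart in retinal EC, and the robust dispersion gave 26 and 16. Tested against a log2 fold change of 1, edgeR called 0, 68 and 86 genes in the 3 comparisons, and 0, 0 and 52 were set apart. Beside the 0 between retinal and brain EC, 580 of 7026 genes had an unadjusted edgeR p under 0.05 against no change, and limma-voom called 8. If no gene differed, a share of 0.05 of the tested genes would still have such an unadjusted p. The covariate left 2 genes set apart in retinal EC. Without R782, R787 and R789 together, which leaves 2 libraries per origin, 2, 174 and 250 genes were called in the 3 comparisons and 198 anywhere, 1, 1 and 126 were set apart (0 of them among the original genes of retinal and of brain EC), and 5 lists were called between retinal and brain EC.

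With an estimated correlation, 2, 1 and 3 lists were called in place of 9, 8 and 10. Fry, which does not compare a list with other genes, called 11, 12 and 14. Counting each gene in 1 list only, 4 lists were called between choroidal and brain EC.

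With each library left out in turn, 4 to 11 genes were called between retinal and brain EC, 205 to 346 between choroidal and brain EC, 275 to 427 between choroidal and retinal EC and 262 to 358 anywhere. Set apart were 1 to 2 genes in retinal, 3 to 9 in brain and 160 to 201 in choroidal EC, and 7 to 10, 6 to 10 and 8 to 11 lists were called. Beyond 1.5 times the original lay retinal against brain EC without R783 (4 genes, 3 of them shared), R787 (5), R784, R785 or R788 (6 each), choroidal against brain EC without R785 (205, 194 of them shared), R786 (209), R788 (231) or R787 (240), choroidal against retinal EC without R783 (275, 258 shared) or R788 (296), and the genes that differed anywhere without R788 (262, 233 shared). The same holds for genes set apart in brain EC without R783 (3), in choroidal EC without R786 (160), R785 or R788 (163 each), and in retinal EC without any of the 9 (1 or 2).

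The other counts of genes lay within 1.5 times the original, among them those with RLE size factors (10, 362 and 455 genes in the 3 comparisons), limma-voom (8, 307 and 359), a fit of 2 groups (14, 298 and 339) and a filter of 5 CPM (10, 337 and 458). Of the calls on named genes, 18 of 62 between choroidal and brain EC and 24 of 75 between choroidal and retinal EC were kept under every alternative run, and none of the 9 between retinal and brain EC. Without the genes of the segments, 146 genes were higher and 109 lower in choroidal than in brain EC, and 203 and 152 than in retinal EC. Segment genes make up 59 and 64 of the lower calls of the report but only 2 and 4 of the higher ones, and the cause of the loss of other higher calls was not tested. With all libraries thinned to one total, 10, 300 and 375 genes were called in the 3 comparisons. Simulated 2-fold changes were found by edgeR in 17.6% to 22.1% of genes, and whether depth or the spread between replicates limits this was not tested.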

Other observations

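The genes of this part were chosen after their values were seen. The fatty acid binding protein Fabp4 was higher in choroidal EC than in brain EC (3.44 ± 0.18, adjusted p = 4.51e-07) and in retinal EC (1.81 ± 0.17, adjusted p = 3.79e-05), and so was the lipid droplet coat protein Plin2 (1.67 ± 0.23 and 1.57 ± 0.23). The lipase Mgll was higher than in retinal EC by 3.66 ± 0.32. The related binding protein Fabp5 was lower than in brain EC (-2.46 ± 0.27) and in retinal EC (-2.88 ± 0.27). Each difference named here was called by edgeR, with 3 libraries per origin.

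The growth factor Igf1 was higher in choroidal EC than in brain EC (1.78 ± 0.20) and in retinal EC (2.95 ± 0.22). The collagen chaperone Serpinh1 was higher by 1.36 ± 0.16 and 1.17 ± 0.16, and elastin (Eln) by 2.56 ± 0.47 and 2.55 ± 0.47. The endothelin receptor Ednrb was lower, at -1.26 ± 0.22 and -1.65 ± 0.22. The caveolae protein Cav1 was called only against retinal EC (1.43 ± 0.20, adjusted p = 0.000849) and not against brain EC (0.43 ± 0.19, adjusted p = 0.25), and whether these differences differ was not tested.

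Of the 14 tested genes of the mitochondrial genome, 12 were below 0 in choroidal EC against brain EC (median -0.758, 3 called lower) and against retinal EC (median -1.06, 6 called lower). These genes are not independent replicates. Mitochondrial genes took 0.489%, 0.816% and 1.16% of the counts of R788, R789 and R790. The share was 0.957% to 1.67% in brain EC, which overlaps with choroidal EC, and 1.18% to 1.67% in retinal EC. The medians with RLE size factors were -0.758 and -1.06. The exceptions were mt-Cytb and mt-Nd2, which were above 0 in both contrasts and not called. Between retinal and brain EC the median was 0.211, with none called by edgeR.

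The libraries R782, R787 and R789 carry barcodes 01 to 03. Their mean read lengths of 1484, 1527 and 1471 bases were the lowest of their origins. These libraries, of which each origin has 1, differed from the other 6 at 8 genes or loci when origin was in the model. Of these 7 were lower, 5 had no reference ID and 0 were among those called between origins. The grouping was chosen after such differences were seen, so this count is no independent test of it.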
